A study of Arabidopsis thaliana with 12 samples.

How the data were processed

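RNA from roots and shoots of Arabidopsis thaliana seedlings was measured on 12 single-colour Affymetrix gene arrays, 1 per sample. Groups and replicate numbers came from the sample titles: 3 arrays each of DMSO roots, estradiol roots, DMSO shoots and estradiol shoots. The treatment text of the labels describes estradiol for all 12 samples, so the titles alone separate the treatments.

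The authors' deposited values are on a log2 scale, 1 per probe set and array, from 0.339 to 14.1, with no missing value. They were made with Affymetrix Expression Console 1.3, per the submitters' processing notes. The summarization, the background correction and the normalization between arrays are not given in the sources used here, and scanner files were not used here. No array was identical to another.

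Probe sets were named through GEO's platform annotation. Of all probe sets, 16722 were paired with 1 gene, 759 with several and 20927 with none. Probe sets with several genes or none were left out of the main tests, so the main results cover 43.5% of the array. The loss is uneven: of the 763 genes in the fixed lists described below, only 118 were measured. Where several probe sets were paired with a gene, the one with the highest mean over the 12 arrays was kept, which gave 16550 genes. Symbols were updated through gene identifiers to the RefSeq gene table of assembly TAIR10.1, which held 16411 of these genes; the other 139 kept the annotation's name. No coordinates were used. Among all probe sets, 5529 repeat an earlier probe set's values on all 12 arrays.

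Tests were run in R 4.3.3 with limma 3.58.1 (lmFit and eBayes) on the values as deposited, with a mean per group, 8 residual degrees of freedom and no filter on dim genes. Contrasts were estradiol against DMSO in roots, the same in shoots, the difference between these effects, and DMSO roots against DMSO shoots. P-values were adjusted by Benjamini-Hochberg over all genes tested, and genes under 0.05 were called; a second count also asked for a 2-fold change. Changes are differences of mean log2 signal with limma's standard error.

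Before the data were examined, 35 gene lists were fixed, with 763 genes in all, of which 118 were measured. The 27 lists with at least 2 measured genes were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation, and with fry. No minimum had been fixed. A first run used at least 3 measured genes and called no list in roots; the minimum of 2 was set after that run, when the values of ARR15 and RR16 had been seen, and the cytokinin call in roots exists only with it. An exploratory test of gene families grouped by symbol called none and is not reported further. Among the 35, 6 lists had no measured gene (CLE receptors, salicylate and pathogen defence, phosphate starvation, ethylene, xylem markers, endodermis and suberin markers) and 2 had only 1 (jasmonate, circadian clock).

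Genes named in the text followed a rule fixed before the data were examined. CLE2 came first. In roots and in shoots, the 12 largest rises and the 12 largest falls were named among called genes whose groups do not overlap, or, with fewer than 10 calls, the 10 genes with the smallest p, as values only. The same fallback served the difference between organs, and the organ contrast gave the 5 largest in each direction. From each list, up to 4 called members were named, and for a called list with fewer than 2 such members the 2 with the smallest p. List members outside this rule (MCCB, APL3, HHO2, HHO3, WRKY6, LBD29, EXPA18) were picked after their values were seen.

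The code was tested on simulated data built from the fitted means and spreads of the 16550 genes, with 200 genes changed in each organ. It recovered 92% of root and 84% of shoot genes changed by 1 log2 unit, 38% in each organ of those changed by 0.6, 100% and 96% of those changed by 1.5, and 100% in each organ of those changed by 2. It called 14 unchanged genes in roots and 7 in shoots. A simulated list of 5 genes shifted by 0.6 was called in shoots, and 0 of 30 unshifted lists were.

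Alternatives covered the organs fitted apart, replicate numbers or seedling sets as blocks, eBayes with trend and robust settings, array weights, quantile normalization, subtraction of array medians, a filter on dim genes, all probe sets, 16 added to the linear value, other thresholds, and each array left out in turn. Outlier tests have little power in groups of 3, and none is reported here.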

Results

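Gene expression was measured on Affymetrix arrays in Arabidopsis thaliana seedlings that carry CLE2 under an estradiol-inducible system. CLE2 encodes a small secreted signalling peptide of the CLE family. The roots of 7-day-old seedlings grown at 22 °C were exposed for 24 h to β-estradiol, labelled as 5 mM, or to the solvent DMSO, and roots and shoots were then collected separately. The 12 arrays fall into 4 groups of 3: DMSO roots, estradiol roots, DMSO shoots and estradiol shoots. The series set out to find genes that act downstream of CLE2, in the treated roots and in the untreated shoots of the same seedlings. No seedlings without the inducible gene were given estradiol, so each comparison holds the effects of estradiol and of CLE2 induction together.

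The values are on a log2 scale. Within a group, the lowest correlation between any pair of arrays was 0.978, and the highest correlation between a root and a shoot array was 0.880. CLE2 itself has no entry among the probe sets paired here with a gene, so its induction was not analysed here and the labels could not be checked by it. Of the 16550 genes tested, 118 belong to the 35 gene lists fixed before the data were examined, which hold 763 genes in all. Most listed genes were thus not measured. All 27 genes called in shoots below carry a locus code in place of a symbol. Thin lists and little-named calls may therefore reflect which genes the annotation pairs with a probe set. The labels do not say whether replicates are separate cultures, so p-values measure only the spread between these samples, which may be technical.

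In the shoots of seedlings whose roots received estradiol, 22 genes rose and 5 fell, out of 16550 (limma, Benjamini-Hochberg adjusted p under 0.05), and 11 of these changed at least 2-fold. The largest rise was that of AT5G19120, an aspartyl protease family gene, which went from 6.73 ± 0.30 to 8.04 ± 0.04 (log2 signal, mean ± SD, n = 3), a 2.48-fold increase. AT2G20670, AT3G07350 and AT4G32480, which encode proteins with the DUF506 domain, rose 2.42-fold, 2.34-fold and 2.24-fold. AT2G20670 went from 6.63 ± 0.35 to 7.91 ± 0.17, AT3G07350 from 5.43 ± 0.30 to 6.66 ± 0.13 and AT4G32480 from 8.15 ± 0.18 to 9.32 ± 0.08. A further DUF506 gene, AT2G38820, also passed the threshold, with a log2 change of 0.93 ± 0.15 (SE); it lies outside the naming rule and was picked after its values were seen. AT1G17147, which encodes the VQ motif protein VQ1, had the smallest adjusted p of all genes in shoots (limma, adjusted p = 0.00824) and rose by 1.07 log2 units, from 6.58 ± 0.19 to 7.65 ± 0.09.

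Regulatory and enzyme genes were among the other large rises in shoots. AT1G36060, an AP2/ERF transcription factor gene, rose by 1.18 ± 0.16 log2 units (SE) from a low DMSO level of 2.61. The RING-type ubiquitin ligase gene AT5G55970 rose by 1.13 ± 0.13 and the PQ-loop membrane protein gene AT4G36850 by 1.09 ± 0.16. AT5G14130, a class III peroxidase gene, rose by 0.94 ± 0.12, and AT3G23470, which encodes a cyclopropane fatty acid synthase family protein, rose by 0.98 ± 0.14. AT2G24550 rose by 1.00 ± 0.14, and AT5G18130 rose 2.29-fold. Limma's adjusted p for these 7 genes lay between 0.0187 and 0.0342. For each of the 12 genes with the largest rises, every estradiol value lay above every DMSO value, which the naming rule required.

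All 5 genes that fell in shoots are named here. AT2G37870 and AT3G53980 encode proteins of the lipid transfer and seed storage protein superfamily: AT2G37870 went from 6.91 ± 0.41 to 5.75 ± 0.10 and AT3G53980 from 9.10 ± 0.27 to 8.10 ± 0.17 (log2 signal, SD, n = 3). AT3G20460, a gene of the sugar transporter superfamily, fell by 0.65 ± 0.10 log2 units (SE). AT4G01703 fell by 0.68 ± 0.10 from a DMSO level of only 3.05, and AT4G08868 fell by 0.58 ± 0.09. All 27 called genes had groups that did not overlap; over all genes 13.2% had such groups in shoots, where chance gives 10% for 3 arrays against 3.

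The number of shoot calls depended on the model and on the arrays fitted together. The main fit shares its spread between organs, and shoot arrays were less alike than root arrays. Their lowest correlation within a group was 0.978, against 0.986 in roots. Standard errors in shoots may thus be too small. A replicate block within each organ gave 20 calls in shoots, with only 12 of the 27 genes among them. With the 6 shoot arrays fitted alone, limma called 0 genes in shoots (1647 genes had an unadjusted p under 0.05 in the fit of all 12 arrays, against 827.5 by chance), and 0 were called without estradiol shoot replicate 1 or without estradiol shoot replicate 3. After each array's median was subtracted, 55 genes were higher and 4 lower, but the subtraction itself moved the median change of all genes from -0.004 to 0.079. Over all probe sets, named or not, 16 were higher and 17 lower, against 22 and 5 in the main split. Identical rows are counted repeatedly there: the falling probe sets 13320387 and 13320405 have 8 and 4 identical rows. With identical probe sets counted once, 26 were called. The median signal of 99 genes that are 5 to 9 log2 units higher in DMSO roots than in DMSO shoots was between 3.73 and 3.81 on the estradiol shoot arrays and between 3.57 and 3.59 on the DMSO shoot arrays.

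**Figure D1:**
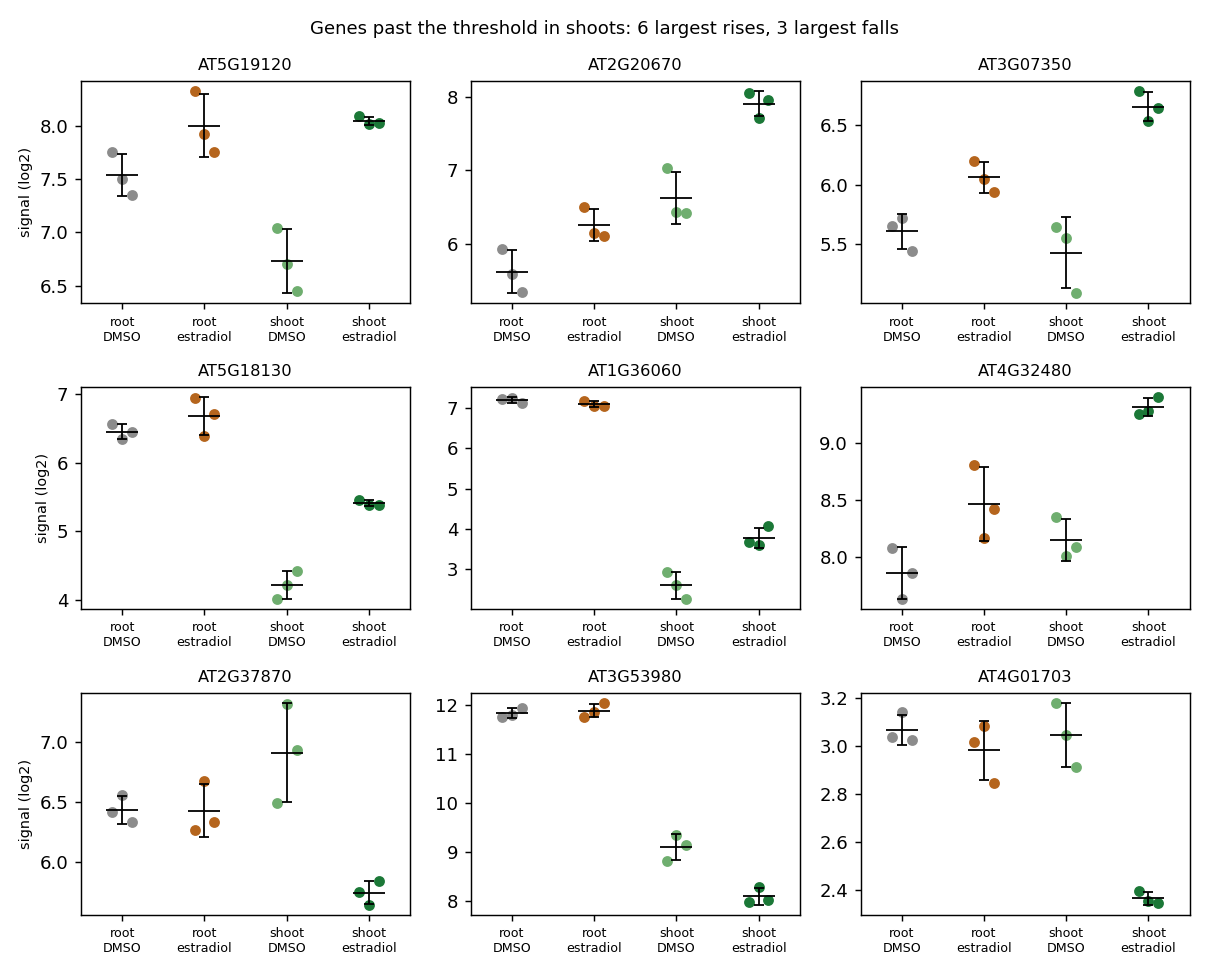
Log2 signal of the 6 genes with the largest rises and the 3 with the largest falls in shoots, by organ and treatment. Points are single arrays (3 per group), horizontal bars are means and error bars are SDs. The estradiol shoot values of AT5G19120 centre on 8.04 and the DMSO shoot values on 6.73, and each panel has its own axis that does not start at 0.

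Among the fixed lists, the sugar starvation and dark-induced genes were higher as a group in estradiol shoots (limma camera, adjusted p = 0.00832 over 27 lists). The call was lost with a correlation estimated from the data (adjusted p = 0.283 with an estimated correlation) and in limma's fry test (adjusted p = 0.0699). Only 3 of its 25 genes were measured, and 0 of them passed the threshold over all genes; adjusted over the list alone, 2 were higher. AKINBETA1, a regulatory subunit of the SnRK1 energy-sensing kinase, was at 8.86 ± 0.30 in DMSO shoots and 9.74 ± 0.31 in estradiol shoots, and the autophagy gene ATG8E was at 6.24 ± 0.37 and 6.77 ± 0.20 (log2 signal, SD, n = 3). MCCB, a subunit of the leucine-degrading methylcrotonyl-CoA carboxylase, had a log2 difference of 0.26 ± 0.13 (SE). The call was also lost without DMSO shoot replicate 2 (camera adjusted p = 0.0739) and without DMSO shoot replicate 3 (camera adjusted p = 0.0523).

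Other lists had an unadjusted camera p under 0.05 in shoots and missed the adjusted threshold. The sugar-induced genes had a median log2 difference of -0.25 over 3 measured genes (camera adjusted p = 0.0970), with APL3, a subunit of the starch-synthesis enzyme ADP-glucose pyrophosphorylase, at -0.52 ± 0.16 (SE). The glucosinolate synthesis genes had a median of -0.37 over 2 genes (camera adjusted p = 0.0674). Their camera adjusted p was 0.0328 with a replicate block within each organ and 0.04996 among genes above the median level. It was 0.0330 without DMSO shoot replicate 1, 0.0432 without estradiol root replicate 1 and 0.191 without DMSO shoot replicate 2. The flavonoid and anthocyanin genes had a median of -0.13 over 7 genes (camera adjusted p = 0.133, fry adjusted p = 0.0313). The nitrate response and nitrogen assimilation genes had a median of 0.21 over 5 genes (camera adjusted p = 0.138). Their mean of 0.17 was 0.26 without estradiol shoot replicate 1 (camera adjusted p = 0.0479) and 0.09 without estradiol shoot replicate 2 (camera adjusted p = 0.343). The 2 members of this list that were higher when adjusted over the list alone were AT1G68670 (HHO2) at 0.51 ± 0.10 and AT1G25550 (HHO3) at 0.30 ± 0.09, both transcription factor genes. Among genes above the median level only these 2 of the 5 were left, with a mean of 0.40 (camera adjusted p = 0.000854). The remaining 22 lists tested in shoots had camera adjusted p between 0.429 and 0.934. Among them, the 7 photosynthesis genes had a median difference of 0.01 and the 4 reference genes a median of -0.05.

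In the treated roots, 0 of 16550 genes passed the threshold (limma, smallest adjusted p = 0.590), and 855 had an unadjusted p under 0.05, against 827.5 by chance. The 10 genes with the smallest p are given as values only. The chitinase family gene AT1G02360 was at 7.34 ± 0.15 in DMSO roots and 6.73 ± 0.11 in estradiol roots, and AT4G12545, of the lipid transfer protein superfamily, was at 8.25 ± 0.24 and 7.23 ± 0.33 (log2 signal, SD, n = 3). AT4G17245, a RING finger gene, was at 7.20 ± 0.22 and 7.93 ± 0.18, and AT3G52070 at 7.83 ± 0.17 and 8.38 ± 0.05. AT5G25280 had a log2 difference of 0.40 ± 0.08 (SE). Differences of -0.80 ± 0.13 for AT1G30140, -0.80 ± 0.14 for the proteasome subunit gene RPN12b, -0.86 ± 0.17 for the GH3 family gene AT1G23160, -0.45 ± 0.09 for the telomere gene STN1 and -0.52 ± 0.10 for the immunophilin gene AT3G10060 complete the set. On simulated data with 200 changed genes and independent noise, the same fit recovered 92% of root genes changed by 1 log2 unit and 38% of those changed by 0.6. With fewer changed genes the adjusted threshold is harder to pass, so these rates do not exclude root changes of that size. AT4G12545, at a difference of -1.01, had an adjusted p of 0.590 (limma).

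Of the fixed lists, the cytokinin response and turnover genes were lower as a group in estradiol roots (limma camera, adjusted p = 0.00244; fry adjusted p = 0.000683). The camera call was lost with a correlation estimated from the data (adjusted p = 0.117 with an estimated correlation). That estimate was -0.73, so the loss does not come from a positive correlation between the measured genes. Both genes were higher in DMSO shoots than in DMSO roots, and without DMSO root replicate 3, which held more shoot signal, the list mean was -0.77 against -0.81 with all arrays (camera adjusted p = 0.0164). Only 2 of its 27 genes were measured, both type-A response regulators that cytokinin induces. ARR15 was at 4.15 ± 0.37 in DMSO roots and 3.27 ± 0.43 in estradiol roots, and RR16 (ARR16) at 4.32 ± 0.15 and 3.58 ± 0.60 (log2 signal, SD, n = 3). Neither passed the threshold over all genes, and both were lower when adjusted over the list alone. The list was tested only because the minimum of 2 measured genes was set after the data, and the values of these genes, had been seen; with a minimum of 3, 0 lists were called in roots. The list could not be tested among genes above the median level, where neither gene lies. In shoots the differences were -0.32 ± 0.21 for ARR15 and -0.13 ± 0.25 for RR16 (SE).

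The senescence and chlorophyll breakdown genes had a median root difference of -0.31 over 3 genes (camera adjusted p = 0.0583), with the transcription factor gene WRKY6 at -0.31 ± 0.09 (SE) and lower when adjusted over the list alone. The list mean of -0.27 was -0.14 without estradiol root replicate 3 (camera adjusted p = 0.367), and the list was called without DMSO root replicate 1 (camera adjusted p = 0.0243) or estradiol root replicate 2 (camera adjusted p = 0.0289). The glucosinolate synthesis genes had a median of -0.27 over 2 genes (camera adjusted p = 0.103); the mean was -0.18 without estradiol root replicate 1 (camera adjusted p = 0.347), and -0.35, and called, without estradiol root replicate 2 (camera adjusted p = 0.0423). The other 24 lists tested in roots had camera adjusted p between 0.548 and 0.884. Among them were the 11 measured genes of the CLE peptide family, with a median root difference of -0.00 and 0 past the threshold, and the 13 sugar transporter genes, with a median of -0.11. DMSO root replicate 3 held more signal of shoot-enriched genes than the other root arrays: the median of 25 such genes was 4.56 there and between 3.53 and 3.89 on the other 5 root arrays. Without that array, 0 genes were again called in roots, and 6 in shoots.

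**Figure D2:**
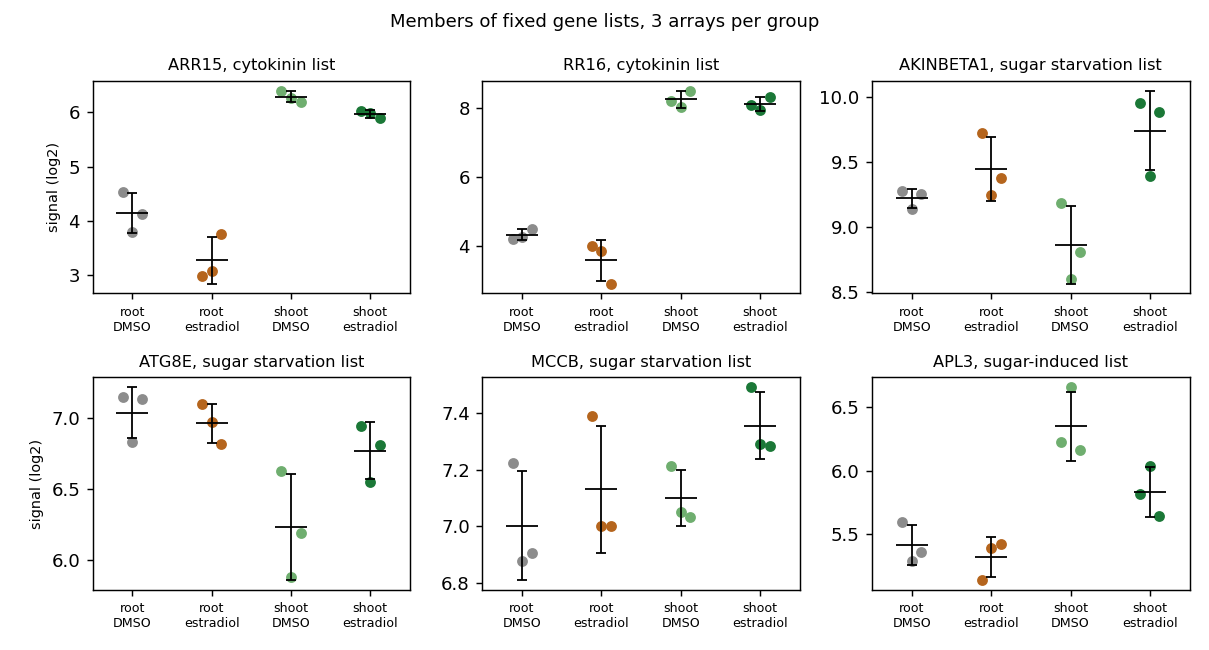
Log2 signal of 6 members of the cytokinin, sugar starvation and sugar-induced lists, by organ and treatment, each panel on its own axis that does not start at 0. Points are single arrays (3 per group), horizontal bars are means and error bars are SDs; ARR15 averages 4.15 in DMSO roots and 3.27 in estradiol roots.

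Whether the estradiol response differed between organs was tested directly. For 0 of 16550 genes did the root and shoot effects differ at the threshold (limma, smallest adjusted p = 0.451), and 895 had an unadjusted p under 0.05, against 827.5 by chance. Of the 10 genes with the smallest p, AT3G09450 had the widest gap, with a log2 difference of 0.59 in roots and -1.24 in shoots (SE 0.23 each). AT1G31163 was at 0.78 and -0.63 (SE 0.17), AT5G39020 at -0.26 and 0.62 (SE 0.12), and AT5G37750 at -0.17 and 0.61 (SE 0.10). AT1G02360 was at -0.61 and 0.30 (SE 0.11) and AT4G05018 at -0.35 and 0.43 (SE 0.09). Of the genes called in shoots, AT1G17147 was at 0.18 in roots (SE 0.10), AT1G36060 at -0.11 (SE 0.16), AT3G20460 at 0.14 (SE 0.10) and AT3G53980 at 0.05 (SE 0.14). No list differed between organs either (0 of 27, limma camera, smallest adjusted p = 0.200; 2 lists, the sugar starvation and the cytokinin genes, had an unadjusted p under 0.05).

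With 0 calls in roots, the root and shoot calls shared 0 genes, where independent calls give 0. Across all 16550 genes, the root and shoot log2 differences had a Pearson correlation of 0.145 and a covariance of 0.00632. These comparisons share no array, and genes are not independent replicates. Roots and shoots came from the same seedlings, and residuals of same-numbered root and shoot arrays correlated at 0.023 to 0.098. Some correlation can thus arise without a response, and its size was not tested.

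**Figure D3:**
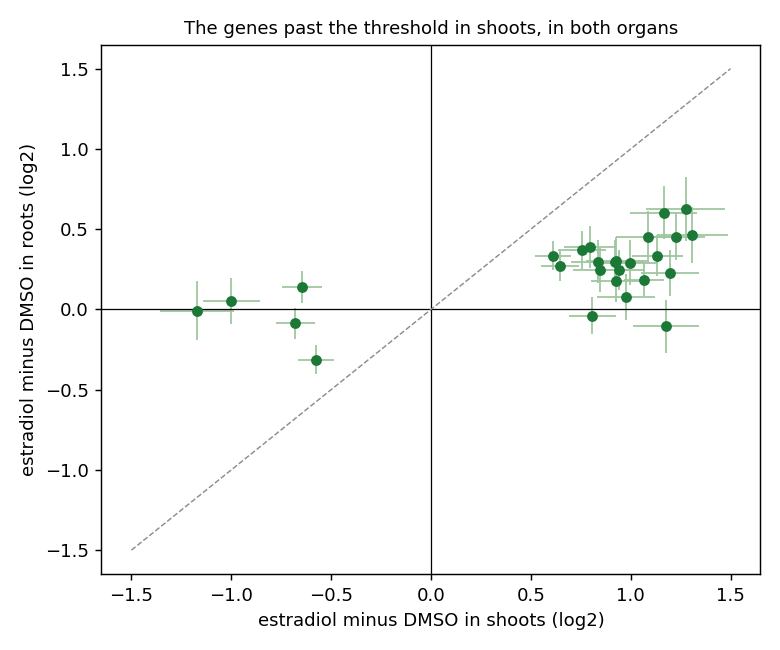
Log2 difference between estradiol and DMSO in roots (vertical axis) against that in shoots (horizontal axis) for the 27 genes past the threshold in shoots. Error bars are standard errors from limma and the dashed line marks equal differences; 23 of the 27 points have the same sign in both organs.

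The organs themselves differed widely. Between DMSO roots and DMSO shoots, 4408 genes were higher and 4277 lower in roots (limma, adjusted p under 0.05), or 52.5% of the genes tested, and 3610 of them differed at least 2-fold. The largest excess in roots was that of the cell wall genes AT3G28550 (11.18 ± 0.12 against 1.91 ± 0.45) and AT3G54580 (11.08 ± 0.18 against 2.61 ± 0.38), both extensin-like, followed by the lectin gene AT1G52060, the β-glucosidase gene BGLU22 and the hydroxyproline-rich glycoprotein gene AT4G38080, with log2 differences of 7.99, 7.95 and 7.86. The largest excess in shoots was that of AT3G16660 and AT3G16670, related to pollen Ole e allergens, with root minus shoot differences of -7.51 ± 0.60 and -7.11 ± 0.49 (SE). The thionin gene AT1G66100, the GDSL lipase gene AT5G33370 and the fatty acid desaturase gene AT1G06100 had differences of -6.78, -6.61 and -6.55. Without DMSO root replicate 3, which held more signal of shoot-enriched genes, the differences were -8.48 for AT3G16660, -7.88 for AT3G16670, -7.08 for AT1G66100, -7.01 for AT5G33370 and -7.19 for AT1G06100.

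The fixed lists gave the organ labels an internal check. All 7 measured photosynthesis genes were lower in DMSO roots, with a median log2 difference of -3.27, and so were the 3 chlorophyll synthesis genes, with a median of -2.52. All 3 lateral root formation genes were higher in roots, among them LBD29 at 3.27 ± 0.20 (SE), as were 2 of 3 root hair markers, with EXPA18 at 4.72 ± 0.34. Both cytokinin response regulators were lower in roots, RR16 by a log2 difference of -3.92 ± 0.25. Of the 4 reference genes, 1 was higher in roots and 0 were lower.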

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

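The tests of the shoot-called genes in roots (fry, permutation and the difference between organs), of shoot RNA in the estradiol roots and of matched random lists in roots, those of risers above their root level and of the share of root RNA each riser needs, and the fit in which identical probe sets count once were chosen after the results were seen. For the array-wide shift between the shoot groups, the prediction was reworded and a condition on random lists dropped after the result was seen. The reference of the riser test was widened from DMSO roots to all roots, and the test of root-enriched genes on AT3G23470 was set to undecided, and DMSO root replicate 3 was left out of the test of shoot-enriched genes, after their results were seen. The other tests in this part were planned.

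Probe sets with no gene or several genes lie outside the main comparisons, and 11 of them passed the threshold in shoots when the 32879 distinct probe sets were fitted together (limma, adjusted p under 0.05). Probe sets 13404737 and 13361537 rose by 1.66 and 1.27 log2 units; in roots their means were 7.78 and 7.60 with DMSO and 8.71 and 8.61 with estradiol. Other unnamed probe sets rose by 1.298, 1.04 and 1.47, and one paired with several genes rose by 0.73. Probe set 13516983 had the deepest fall of these, with a log2 change of -2.39, and 13320387, whose values recur in 8 identical rows, had -1.08. The others changed by -1.05, -0.66 and -1.51.

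The shoot response to estradiol given to roots is a pattern a biologist would want to follow up. Root tissue among the estradiol shoots is argued against for 8 of the 22 risers, whose estradiol shoot values all lay above all their root values with either treatment (AT1G23390, AT2G20670, AT2G38820, AT3G07350, AT3G21460, AT4G32480, AT4G36850 and AT5G38386). It is argued against as the whole cause for 13 of the other 14, with AT5G19120 among them: even at 2 SE below the estimate they would need at least 2.45% root RNA, and that share predicts a median rise of at least 1.08 in 99 root-enriched genes, with a lower quartile of at least 0.90. The median change of those genes was 0.049, with an upper quartile of 0.35. For AT3G23470 it stays open, since a share of 0.647% predicts a median of only 0.39, the genes lie near the floor, and their median signal was 3.73 to 3.81 on the estradiol shoot arrays against 3.57 to 3.59 on the DMSO shoot arrays. The deposited values hold no shift of all genes as large as the called changes, since the median shoot change of the 16550 genes was -0.004. The normalization between arrays is unknown and may itself have brought this median near 0. A shift before that step therefore stays open. With quantile normalization 32 genes were called, 25 of the 27 among them. After each array's median was subtracted 59 were called, 26 of the 27 among them. That count cannot decide, since the subtraction moved the median change to 0.079 and 55 of the 59 were rises. What also stays open is chance, since 10 splits of 6 arrays are too few for a share under 0.05 (27 genes in the real split, the only 1 of the 10 with as many, and at most 1 gene in any other), and whether estradiol itself or CLE2 acts, for which no group exists.

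The 27 genes called in shoots also had the same sign in roots in 23 cases, and 12 of them had an unadjusted root p under 0.05 (limma). Taken with their shoot signs, they differed in roots by 0.25 log2 units on average (limma fry in roots, p = 0.00165; an exact two-sided permutation of the root labels gave 0.1, the smallest p that 20 relabellings allow). An array-wide shift in roots is argued against, since 0% of 10000 random lists matched on mean level reached this difference. Shoot tissue among the estradiol roots is argued against for 10 of the 27, taken as a set. These were higher in DMSO roots than in estradiol shoots, so that shoot RNA would lower them. Of these, 9 were higher in estradiol roots, and the 10 differed by 0.22 ± 0.14 (SD over genes), or by 0.21 without DMSO root replicate 3, which held more shoot signal. The exception, AT1G36060, differed by -0.11, the direction that shoot RNA would bring, so for this gene shoot tissue stays open. For the other 17 it stays open, since 25 genes over 5 log2 units higher in shoots had a median root difference of -0.14 with all arrays but of 0.085 without that replicate, with an upper quartile of 0.29. Noise shared by roots and shoots of the same seedlings could also move genes picked in shoots the same way in roots. Residuals of same-numbered root and shoot arrays correlated at 0.023 to 0.098, and the fry test does not allow for this. Its size was not tested. A response of the same genes in both organs may be a candidate explanation, as a hypothesis found on these data. Estradiol and CLE2 cannot be separated in it. A test of the difference between organs on these genes was run with fry (signed mean -0.70) and set aside as circular, since the genes were picked for their shoot change.

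In roots, 0 genes were called, at most 1 in any other split of the 6 arrays, and all 10 splits gave as many; for the difference between organs, all 100 drawn splits gave at least the 0 genes of the real one, with at most 1. Between DMSO roots and DMSO shoots, 1 of 10 splits (the real one) gave 8685 genes and the others 0. One list was called in shoots, where 3 of 10 splits gave as many and the highest other gave 3, and 1 list in roots, where 4 of 10 splits gave as many and the highest other gave 1. For the difference of lists between organs, all 100 drawn splits gave at least the real 0, with at most 4. Splits of 3 against 3 are too few for a share under 0.05.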

How the results depend on the processing

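The counts for probe sets counted once when identical and for lists of at least 3 genes, and all settings of the signed root difference of the shoot-called genes, were chosen after seeing the data. In roots, 0 genes were called under every alternative run. Named genes kept their direction under every alternative run; the 17 genes named as called in shoots kept their call in 200 of 388 combinations of gene and setting and lost it in 188, and those of the organ contrast lost it in 0.

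The shoot count of 27 moved most. It was 91 with eBayes trend and robust settings, 7 with array weights, 59 with array medians subtracted, 73 among genes above the median level, 77 with 16 added to the linear value, and 0 with shoots fitted alone; 25, 7, 26, 21, 25 and 0 of the 27 were among them. At adjusted p 0.1 it was 82, at 0.01 it was 1, and with a 2-fold minimum 11. Leaving out an array gave 0 to 19: 0 without estradiol shoot replicate 1 or 3 and 17 without replicate 2; 6 without DMSO shoot replicate 2 or 3; 7, 3 and 6 without estradiol root replicates 1, 2 and 3; and 1 and 6 without DMSO root replicates 2 and 3. Fewer arrays leave fewer residual degrees of freedom. The shared spread also lets the more uniform root arrays lower the standard errors in shoots. How far either accounts for the counts was not tested. Over all probe sets it was 33, with 12 of the 27 genes among them, and 26 with identical probe sets counted once.

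The difference between organs gave 1 gene with trend and robust settings (AT1G17147), and 0 to 1 when arrays were left out (1 without DMSO shoot replicate 2). The organ contrast gave 5681 genes above the median level, where fewer genes were tested, 3610 with a 2-fold minimum, 17967 over all probe sets and 17041 with identical ones once, where more were tested, and 7839 to 8739 without an array. The root list count of 1 was 0 with an estimated correlation, with fry's mixed test, with lists of at least 3 genes and among genes above the median level, and 1 to 3 without an array (2 without DMSO root replicate 1, 3 without estradiol root replicate 2). The shoot list count of 1 was 0 with an estimated correlation and with fry's mixed test, 1 with fry's directional test for another list (flavonoid), 3 among genes above the median level, and 0 to 2 without an array (0 without DMSO shoot replicate 2 or 3, 2 without DMSO shoot replicate 1, estradiol shoot replicate 1 or estradiol root replicate 1). The cause was not tested. The signed root difference stayed between 0.195 and 0.303 over all settings run, with fry p from 1.41e-05 to 0.0123.

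The replicate numbers were not taken as pairs: residual correlations of same-numbered arrays ran from 0.023 to 0.137 and passed 0.1 in 2 of 12 pairs, though all 12 were highest with their own number, a hint from the data. With a replicate block within each organ, 0 genes were called in roots, 20 in shoots (12 of the 27 among them), 0 for the difference between organs and 8693 between organs, with 1 list in roots, 2 in shoots and 0 shared genes. A replicate block shared by both organs gave 0, 39, 0 and 8854 genes.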

Other observations

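The DUF506 comparison below was chosen after the shoot calls were seen. Arabidopsis has a family of genes for proteins with the DUF506 domain, and all 13 members listed from general knowledge were measured. In estradiol shoots, 12 of the 13 had a positive log2 difference, from -0.16 to 1.28 with a median of 0.30, and 4 of them were called. Among those not called, AT4G14620 had a difference of 0.51 and AT1G62420 one of 0.35 ± 0.22 (SE). AT1G62420, AT1G77145, AT1G77160 and AT3G54550 lay near the floor. Their shoot means ran from 1.93 to 2.89, below the lower quartile of every shoot array (3.55 to 3.63). In estradiol roots, 9 of the 13 were positive, with a median of 0.16 (limma camera over all 13, p = 0.00727, and p = 0.0462 with an estimated correlation). The 4 called in shoots were at 0.63, 0.30, 0.45 and 0.60 in roots. Members not called in shoots ran from -0.67 to 0.29 in roots, and all negative root differences were among them. They were not tested on their own in roots.

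A candidate explanation for the 4 called genes is that the family is higher as a whole in these shoots. The 9 members that were not called had a median shoot difference of 0.28, with 8 positive (limma camera, p = 0.00122, and p = 0.00989 with an estimated correlation). Some of these 9 lay near the floor, as given above. The family was picked from the calls on these same arrays and split by them, and AT4G14620 missed the threshold narrowly (limma, adjusted p = 0.0929), so this is no independent test; related sequences may share probe signal, which was not tested.

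Whether the shoots responded as in sugar shortage was left open. The sugar starvation call rests on 3 of 25 genes, with 0 past the threshold, and was lost with an estimated correlation (adjusted p = 0.283 with an estimated correlation), in fry (adjusted p = 0.0699) and without DMSO shoot replicate 2 or 3. A second list of 8 sugar starvation markers was written without sight of their values, but 0 of them had a probe set paired with a single gene.

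The largest changes in roots belonged to probe sets with no gene name here. Of the 4 with the smallest p, log2 differences were 2.13 ± 0.27, 1.55 ± 0.19, -2.34 ± 0.28 and -1.01 ± 0.13 (SE), and none passed the threshold over the distinct probe sets (limma, adjusted p = 0.105). The probe set at 2.13 had the largest rise in roots of all, from 5.55 ± 0.25 to 7.69 ± 0.57 (log2 signal, SD, n = 3), and its shoot means were 8.72 with DMSO and 9.02 with estradiol. The probe set at -2.34 went from 5.41 ± 0.33 to 3.07 ± 0.56 in roots and was at 7.79 and 8.05 in shoots.

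On DMSO root replicate 3, the shoot-enriched genes AT3G16660, AT3G16670 and AT1G06100 were at 6.68, 5.69 and 4.98, against at most 4.05, 3.77 and 3.46 on the other root arrays.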
